A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

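Messenger RNA was measured by RNA sequencing in 4 libraries, 2 of the reference strain CEN.PK113-7D and 2 of the minimal glycolysis strain IMX372. Groups were taken from the strain label. Replicate numbers were given in the order of the samples and pair nothing. Per the labels' protocols, complementary DNA was made into libraries with a kit that does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The labels describe single reads of 51 bases on a HiSeq instrument in 1 place and a paired-end protocol in another.

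Per the submitters' processing notes, CASAVA 1.8.2, BWA 0.5.9-r16, SAMtools 0.1.7-r510, Cufflinks and Cuffdiff were used, with no role or order given, and per the labels the CEN.PK113-7D genome served all analyses. The deposited file is a table of the authors' comparison in the layout of Cuffdiff. It holds an FPKM per gene model for each strain, which the authors pooled over that strain's libraries. It also holds the authors' log2 ratio of the minimal glycolysis strain over the reference, and the authors' p-value and q-value. Per the file headers, its columns give 1 value per strain, so neither library sizes, nor values per library, nor an SD can be given. Low FPKM values, multiplied by coding length, showed no common step from which reads could be counted, so the depth per gene is unknown and no counting interval is given. The number of columns with per-sample values left unused was 0.

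The file lists 5472 gene models, of which 5437 have the test status OK, 32 were not tested and 3 exceeded the authors' limit on data (FBA1, TDH3 and TEF1). Of the models, 97.2% have a length that is a multiple of 3, so lengths are coding lengths without untranslated regions. Coordinates are those of the file on the CEN.PK113-7D assembly, counted from 1. Gene symbols were taken from the R64 annotation of the S288C reference through the systematic names in the file, which matched for 5434 models, and 34 models have no name. R64 was used for names, for which genes are neighbours and for GC content, and none of its coordinates is printed. Names in the file rest on the authors' matching, and 72 systematic names stand on 149 models. A 0 in a model that was not tested or exceeded the limit was not read as a measurement, since genes that every yeast cell uses are among them. GPM3 was tested and called by the authors, so its 0 was taken as their value. No fold against a 0 is printed, but GPM3 was counted among changes of at least 2-fold.

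A model was called different when its status was OK and the authors' q was at most 0.05. The q comes from the authors' Cuffdiff test across all models, and no test across libraries could be run on pooled values. Folds and log2 ratios were computed from the FPKM without a pseudocount and differ from the authors' log2 by at most 1.31e-05. For lists and regions, 1 model per gene was kept, the longest tested one, which left 5362 genes with a ratio. Each list was tested with Fisher's exact test, two-sided, of called against not called genes, list against all other genes, with Benjamini-Hochberg adjustment over lists. The median log2 ratio of a list was placed among those of 10000 random lists with the same number of genes from each of 20 expression bins. Chromosomes and windows of 20 consecutive genes, in steps of 10, were set against 10000 random gene sets of the same size, with Benjamini-Hochberg adjustment over chromosomes. The nearest tested gene on each side of the deleted loci was found by gene order in R64. Genes are not independent replicates, so these tests describe the libraries at hand.

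The lists, the tests and the rule for named genes were fixed before the data were examined. The rule names all members of the lists of deleted paralogs, retained paralogs and marker genes. It adds the 12 largest and the 12 smallest log2 ratios among called models with an FPKM of at least 10 in the higher strain, outside those lists. Of each other list it names up to 4 called members by absolute log2 ratio, or up to 2 members as values where none was called, and it names the called nearest neighbours of the deleted and marker loci. Only 11 models met the rule for the smallest ratios. Of the genes the rule selects, 2 are not reported here.

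Alternatives fixed in advance were a q of 0.01, a change of at least 2-fold, an FPKM of at least 10 in a strain, recomputed q-values, centring on the median, 1 or 5 FPKM added before the logarithm, lists without the A and B copies of paralog pairs, lists adjusted alone, 2 neighbours per side, windows of 10 and 40 genes, and the mean in place of the median. Alternatives without the 2 blocks, per gene for calls, per model for chromosomes and windows, and with the log2 ratio corrected for expression level, coding length and GC content were chosen after seeing the data. The correction fits polynomials of degree 3 in each property to the genes that were not called, used 99.3% of genes and fitted 12.7% of the variance. The steps were tested on simulated data with 5362 genes, 200 of them changed by 1 on the log2 scale. Of these, 99.5% were called, the list and the block that had been moved were recovered, and 0 other lists passed Fisher's test. Of the calls, 7.33% were on unchanged genes, and 2 other lists had a median outside the range of random lists. The simulated ratios were independent normal draws, and their p-values used the known spread. These shares therefore check the list and block steps and say nothing about the authors' Cuffdiff test. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.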

Results

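The transcriptome of a Saccharomyces cerevisiae strain with a reduced set of glycolytic genes was compared with that of its reference strain. The reference, CEN.PK113-7D, is a prototrophic haploid laboratory strain of mating type a. The minimal glycolysis strain, IMX372, carries deletions of 13 minor paralogs of glycolysis and alcoholic fermentation, per the genotype label, and keeps the major ones. The same label gives it mutant alleles of LEU2, URA3 and HIS3 and a Kluyveromyces lactis LEU2 marker. Effects of these differences cannot be told apart from effects of the deletions. Per the labels, both strains were grown in aerobic batch bioreactors in synthetic medium with 20 g/L glucose at pH 5 and 30 °C, and RNA was taken in mid-exponential phase. Each strain has 2 libraries, from a design of 4 independent cultivations per strain. The deposited table gives 1 FPKM per gene model and strain, pooled by the authors over the libraries, so no SD or n accompanies any value below. The authors' q-value rests on Cuffdiff's estimate of the spread between the libraries of a strain, and how it was estimated is not stated. The labels do not state outright that these libraries come from different cultivations. The labels state at least 1 Gb of 51-base reads per data set, and read numbers per gene are not given by the table. The table covers 5472 gene models predicted on the CEN.PK113-7D assembly, of which 5437 were tested by the authors.

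The deletions come first, since they check the strain labels. GPM3, a minor phosphoglycerate mutase gene (chromosome 15, 223118 to 224029), had an FPKM of 57.7 in the reference, was listed at 0 in the minimal glycolysis strain, and was called lower with q = 0.00735 in the authors' deposited table. A further 10 deleted genes, GLK1, HXK1, TDH1, TDH2, GPM2, ENO1, PYK2, PDC6, ADH4 and ADH5, were listed at 0 in both strains and were not tested by the authors. TDH2 and ENO1 encode abundant glycolytic enzymes, so a 0 in the reference is not a measurement of its expression. The sample names in the table end in the word masked, and the sources used here do not say what was masked. PDC5 and ADH2 have no model under those names and were not analysed here. The table therefore checks 1 of the 13 deletions.

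The question of the comparison was what the loss of all minor paralogs, together with the marker differences, does to expression elsewhere, and few genes were called. By the authors' deposited table, 43 models passed a q of 0.05, which is 0.791% of those tested, with 28 higher and 15 lower in the minimal glycolysis strain. Of the 28 higher models, 19 lay in 2 blocks of neighbouring genes on chromosomes 3 and 5. The remaining calls included BAP3 and CWP1 among the higher genes, and GPM3, LEU2, ASP3-1 and FIT3 among the lower ones. The log2 ratio of minimal glycolysis over reference lay within 0.5 of 0 for 98.2% of the tested models with a value in both strains, and its median was 0.01. The smallest change that was called was 1.57-fold. No limit of detection was measured, and it need not be the same for every gene. OYE3, at an FPKM of 4.32 in the reference, had a log2 ratio of -0.86 and was not called (q = 0.219 in the authors' deposited table). By the authors' deposited table, 178 tested models had an unadjusted p under 0.05, 103 higher and 75 lower. This is fewer than a share of 0.05 of the 5437 tested, which evenly spread p-values would give without any difference. The count is thus no sign of further differences. It also leaves open that the test was cautious, so few calls need not mean few changes. The test was the authors' Cuffdiff comparison, in which 37 models share the smallest p of 5e-05.

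**Figure D1:**
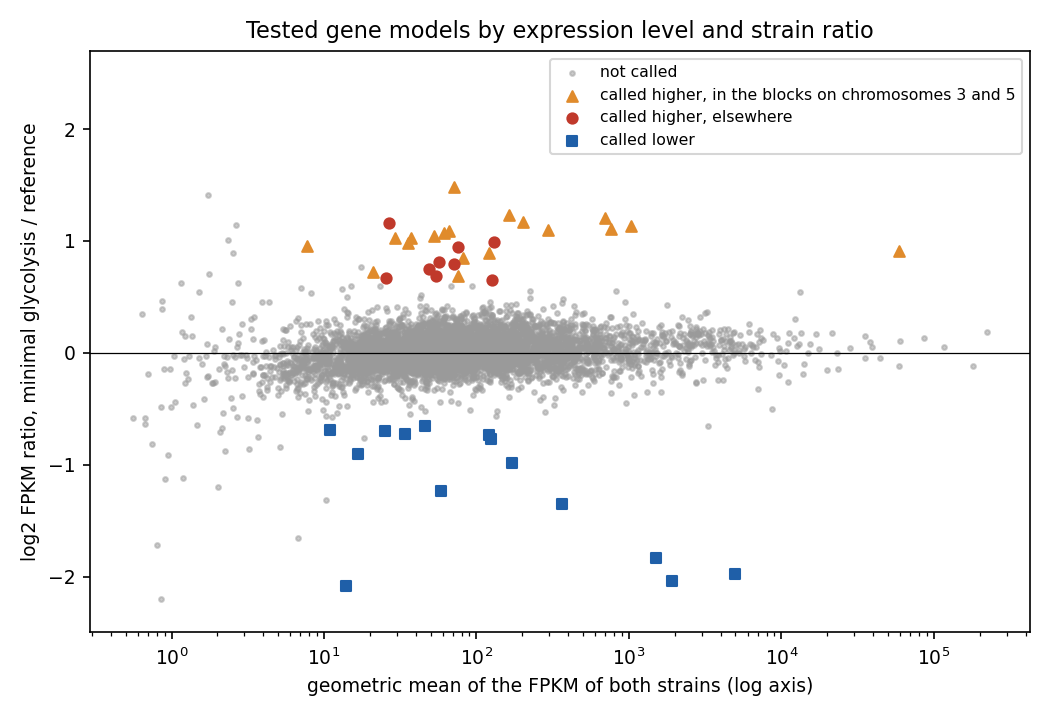
The plot shows the log2 FPKM ratio of minimal glycolysis over reference (vertical) against the geometric mean FPKM of both strains (horizontal, log axis) for each tested gene model with a value in both strains. Grey points were not called, orange triangles are the 19 called models in the blocks on chromosomes 3 and 5, red circles are the 9 other models called higher and blue squares are models called lower. Each point rests on 1 pooled value per strain.

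The 2 blocks had similar median rises, while their single genes varied. On chromosome 3, 10 consecutive tested models from MAK32 to RHB1 (152512 to 167673, CEN.PK113-7D assembly) were all called higher, by 1.61-fold to 2.31-fold with a median of 2.05-fold. They include HTL1, a subunit of the RSC chromatin remodelling complex, at 2.31-fold, and MAK31, MAK32 and PET18 at 2.15-fold, 2.13-fold and 2.10-fold. NPP1, a nucleotide pyrophosphatase gene, rose 2.07-fold and HSP30, a stress protein of the plasma membrane, 2.03-fold. On chromosome 5, 9 consecutive tested models from PUP3 to RTT105 (346957 to 365521) were all called higher, by 1.65-fold to 2.79-fold with a median of 2.13-fold. RTT105 rose 2.79-fold and PRS2, a phosphoribosyl pyrophosphate synthetase gene, 2.35-fold. PUP3, a proteasome subunit gene, UBC6, a ubiquitin-conjugating enzyme gene, AST2 and SSA4, a stress-inducible Hsp70, rose 2.20-fold, 2.13-fold, 2.03-fold and 1.98-fold. The blocks also hold YCR023C, SLM5, PMP1, RHB1, SHC1 and UBP9, which the naming rule did not select and which were chosen after their values were seen. They rose between 1.61-fold and 1.93-fold. The 20 tested models flanking the chromosome 3 block had a median log2 ratio of -0.05 and those flanking the chromosome 5 block of -0.04, with 0 called in either, the highest being AIM11 next to the chromosome 5 block at 0.41. The q of all 19 block genes was 0.00735 in the authors' deposited table.

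**Figure D2:**
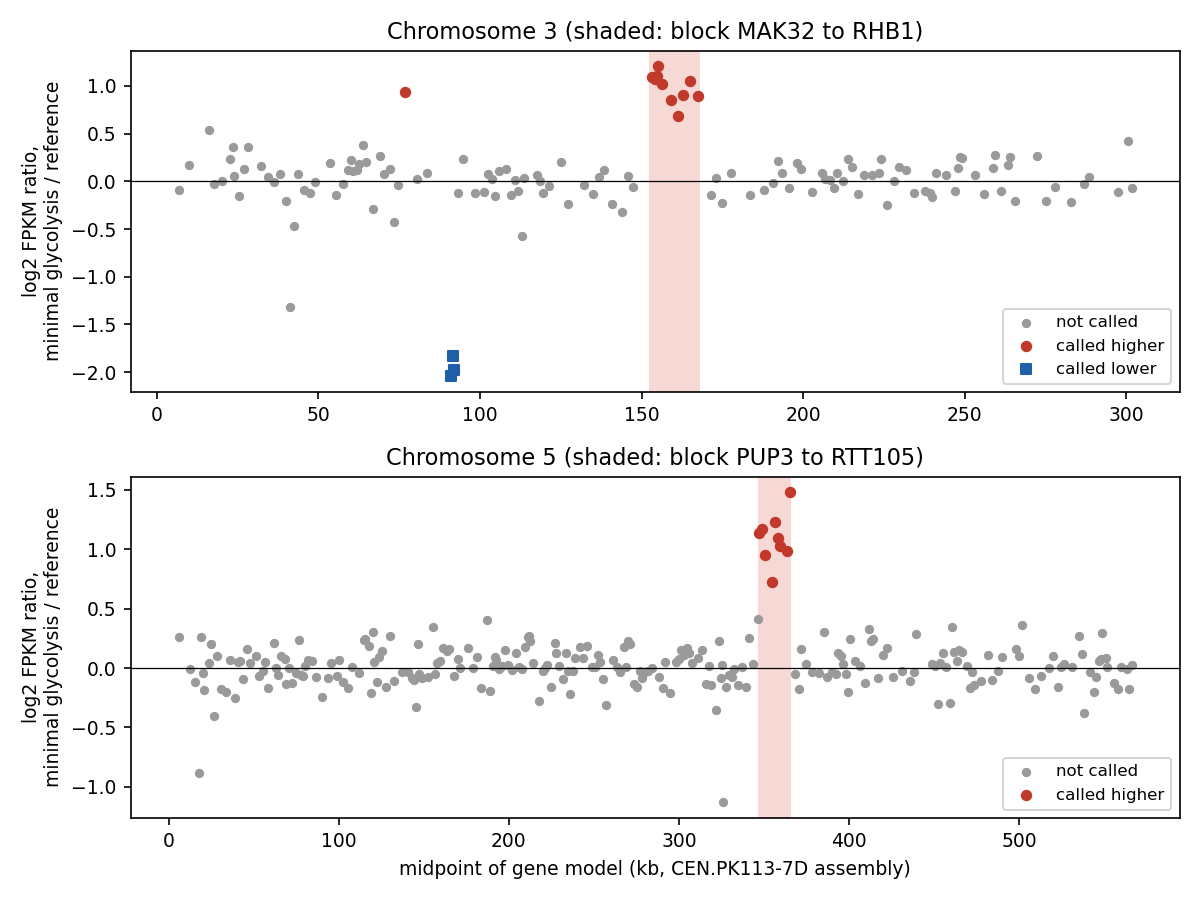
The log2 FPKM ratio of minimal glycolysis over reference (vertical) is plotted against the position of each tested gene model on chromosomes 3 and 5 (kb, CEN.PK113-7D assembly). The shaded blocks span 15.2 kb and 18.6 kb and hold 10 and 9 models called higher (red), the further red point on chromosome 3 is AGP1, and the 3 blue squares on chromosome 3 are the models named LEU2.

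Outside the blocks, 9 genes were called higher. BAP3, a branched-chain amino acid permease gene, rose 2.24-fold, from an FPKM of 17.9 to 40.1. CWP1, a cell wall mannoprotein gene, rose 1.98-fold, CTR3, a copper transporter gene, 1.75-fold, ZRT1, a high-affinity zinc transporter gene, 1.68-fold and PHO3, a thiamine-repressible acid phosphatase gene, 1.59-fold. The others, chosen after their values were seen, were the amino acid permease genes AGP1 at 1.92-fold, DIP5 at 1.73-fold and GNP1 at 1.57-fold, and BDS1, a sulfatase gene, at 1.61-fold. Their q in the authors' deposited table was 0.00735, except for PHO3 and GNP1 at 0.0139, which a q of 0.01 would not call.

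Among the lower genes, LEU2, the beta-isopropylmalate dehydrogenase gene used as an auxotrophic marker, fell to between 0.242 and 0.281 of the reference level in the 3 short models that carry its name on chromosome 3. Their FPKM went from 3866 to 937, from 2841 to 798 and from 9880 to 2503. The genotype label gives the minimal glycolysis strain a mutant leu2 allele and a Kluyveromyces lactis LEU2 marker. URA3 and HIS3, also mutant in that genotype, were not called, at log2 ratios of 0.23 and -0.02. YLR159W, ASP3-1, a cell wall asparaginase gene, and RSC30 had log2 ratios of -2.09, -1.35 and -0.74. These 3 models are listed one after another on the sequence the table lists as chromosome 0. It holds 8 models, among them the genes R0010W and R0030W of the 2-micron plasmid, and what it is made of is not stated, so the order need not be that of a chromosome. ASP3 exists in near-identical tandem copies in the R64 reference, so the value of ASP3-1 can hold reads of several copies. By their systematic names, YLR155C and YLR159W, ASP3-1 and YLR159W lie near each other on 1 chromosome arm of R64. These 2 calls therefore need not be independent. FIT3 and FIT2, cell wall mannoproteins that retain siderophore iron, fell to 0.424 and 0.585 of the reference level. MEP2, an ammonium permease gene, and PDR12, a weak-acid efflux pump gene, fell to 0.506 and 0.535 of it. TIS11, which targets messenger RNAs for decay under iron deficiency, YRO2, UBP15, a ubiquitin protease gene, and BNA2, a gene of NAD synthesis from tryptophan, fell to between 0.605 and 0.635 of it. In the authors' deposited table the q of these lower genes was 0.00735, except for TIS11, UBP15 and BNA2 at 0.0194 and YRO2 at 0.0316, which a q of 0.01 would not call.

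The retained major paralogs were asked whether they took over from the deleted genes. None of the 10 with a usable value rose, and none was called. Among them only HXK2, GPM1, CDC19, PDC1 and ADH3 had a deleted paralog, so the others cannot answer that question. All 10 had log2 ratios below 0, between -0.32 for PGK1 and -0.11 for TPI1, with a median of -0.18. GPM1, the most abundant of these 10, went from an FPKM of 14825 to 12976, PGK1 from 7876 to 6297, CDC19, the pyruvate kinase gene, from 4493 to 3786 and PDC1, the pyruvate decarboxylase gene, from 4601 to 4190. HXK2, PGI1, PFK1, PFK2 and ADH3 had log2 ratios of -0.13, -0.11, -0.24, -0.20 and -0.18. In the authors' deposited table the smallest unadjusted p among the 10 was 0.114 for PGK1, and 0 genes passed when adjusted over the list alone, where the smallest Cuffdiff p was 0.56. None of the 10 genes therefore passed singly in the authors' test, which does not show that they were unchanged. As a list, their median lay below that of all 10000 random lists matched on expression, whose central 95% ran from -0.05 to 0.14. Such shifts were common, since 15 of the 39 testable lists had a median outside that range, 13 below and 2 above. FBA1 and TDH3 carry the authors' status for too much data. Both are listed at 0 in the minimal glycolysis strain, which is not a measurement. ENO2 and ADH1 were not analysed here, so for TDH3, ENO2 and ADH1 the question stays open.

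**Figure D3:**
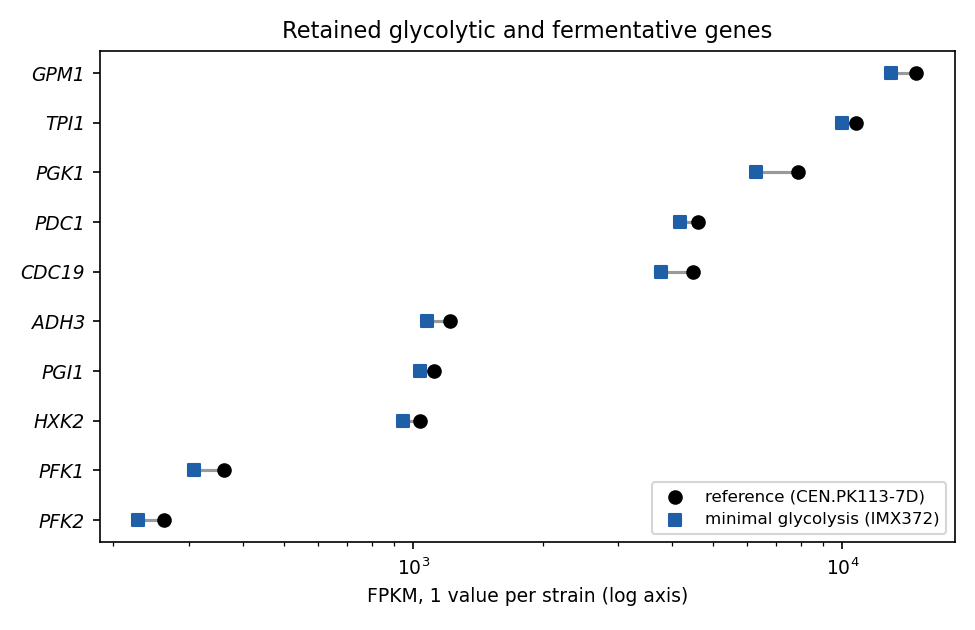
The plot shows the FPKM (horizontal, log axis, 1 pooled value per strain) of the 10 retained paralogs with a usable value in the reference (black circles) and the minimal glycolysis strain (blue squares). Each minimal glycolysis value lies below its reference value, by log2 ratios from -0.32 to -0.11, and no difference was called.

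Of the 40 gene lists fixed before the data were examined, 39 had at least 3 tested members, and 1 passed the adjusted Fisher's exact test for its share of called genes. This was the iron regulon list, built around genes of iron uptake and iron economy that the transcription factors Aft1 and Aft2 control. CTR3 was higher and FIT3, FIT2 and TIS11 lower among 23 tested members (Fisher's exact test, two-sided, p = 2.1e-05, adjusted p = 0.000828). FIT2 and FIT3 are neighbours on chromosome 15. TIS11 lies on chromosome 12 just beyond SLX4, the nearest tested gene to the right of the deleted PDC5 locus. These calls therefore need not be independent. The list's median log2 ratio was -0.38, with 20 members below 0 and 3 above. It lay below all matched random lists, whose central 95% ran from -0.07 to 0.08. Adjusted over the list alone, 11 members passed as lower and 1 as higher. The 8 that joined the called ones were CCC2, HMX1, FRE2, ARN1, FET3, FRE1, SIT1 and ENB1, with log2 ratios between -0.55 for CCC2 and -0.39 for ENB1. FET3, the multicopper oxidase of high-affinity iron uptake, went from an FPKM of 381 to 276. CTR3 and CTR1, at log2 ratios of 0.81 and 0.18, are copper transporter genes that this list includes. Fisher's test ignores direction, so it counts CTR3 with the called members although CTR3 was higher. FIT1, at 0.30, had an FPKM of 3.01 in the reference.

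**Figure D4:**
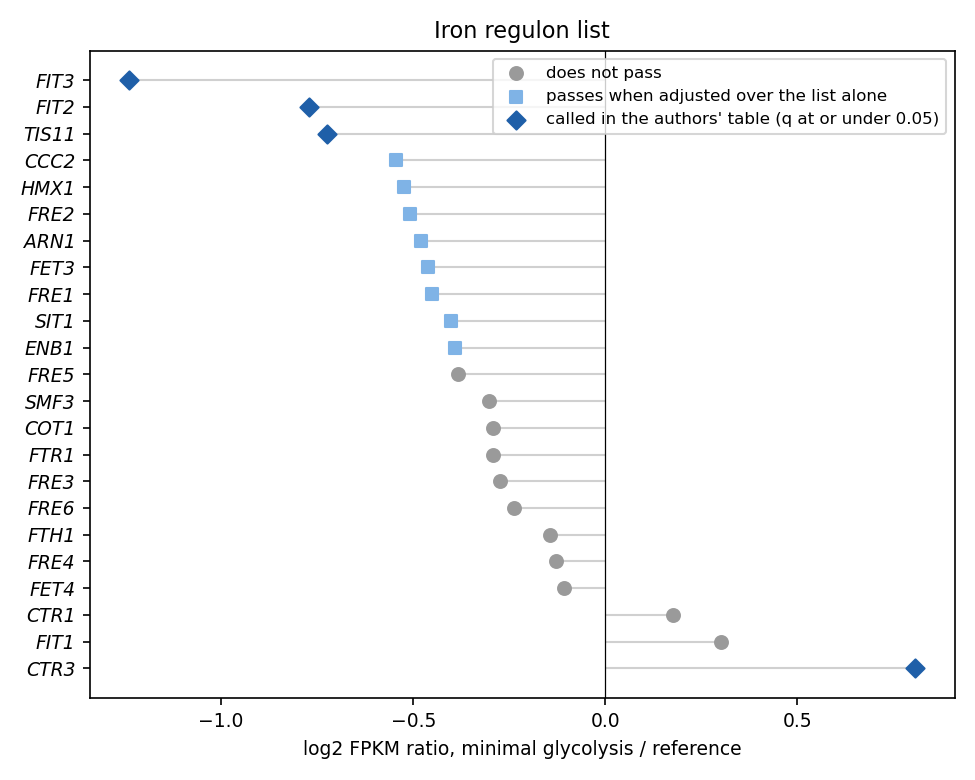
The plot gives the log2 FPKM ratio of minimal glycolysis over reference (horizontal) for the 23 tested genes of the iron regulon list. Dark blue diamonds were called in the authors' deposited table, light blue squares passed when adjusted over the list alone and grey circles did not pass, and 20 genes lie below 0.

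In 7 other lists that held called genes, the share of called members did not pass Fisher's exact test after adjustment. When adjusted over the list alone, the same members passed in each. In the nitrogen catabolite list, ASP3-1 and MEP2 were called lower among 27 tested members (Fisher's exact test, adjusted p = 0.165), and 25 members had log2 ratios below 0, with a median of -0.14 that became -0.08 after a fit on expression level, coding length and GC content. In the thiamine and pyridoxine list, PET18 and PHO3 were called higher among 16 (Fisher's exact test, adjusted p = 0.119), and its median of -0.12 and mean of 0.01 differ in sign. PET18 lies in the chromosome 3 block. The medians of the nitrogen catabolite and thiamine lists lay below the central 95% of matched random lists. In the general stress list, HSP30 and SSA4 were called higher among 26 (Fisher's exact test, adjusted p = 0.165). Both lie in the blocks, and the list's median of -0.03 and mean of 0.07 differ in sign. Its median was 0.004 with genes of an FPKM of at least 10 and 0.002 after the fit. ZRT1 was the 1 called gene of 16 in the zinc list, whose median of -0.04 and mean of 0.06 differ in sign and whose median was 0.04 with genes of an FPKM of at least 10, PDR12 the 1 of 16 in the multidrug transporter list and CWP1 the 1 of 31 in the cell wall list (Fisher's exact test, adjusted p = 0.63, 0.63 and 1). LEU2 was the 1 of 3 marker genes (Fisher's exact test, adjusted p = 0.173).

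Central carbon metabolism outside glycolysis held no called gene. The TCA cycle list had 17 of 18 members below 0 with a median log2 ratio of -0.11, led by SDH4 at -0.24 and ACO1 at -0.23. The pentose phosphate list had a median of -0.16, with NQM1 and GND2 at -0.42 and -0.33, and the hexose transporter list one of -0.14, with HXT3 at -0.45 and HXT4 at -0.38. These 3 medians lay below the central 95% of matched random lists, at the 0, 0.4 and 0.68 percentiles. The hexose transporter list no longer did so with genes of an FPKM of at least 10, at a median of -0.08, or with 1 FPKM added, at -0.09. After the fit on expression level, coding length and GC content the medians of the TCA cycle, pentose phosphate and hexose transporter lists were -0.14, -0.11 and -0.08, at the 0.04, 2.13 and 1.98 percentiles, and those of the glyoxylate and the trehalose lists were -0.02 and -0.01. The median of the glyoxylate cycle and gluconeogenesis list lay inside that range, at -0.07, with MDH2 at 0.60 and SIP4 at -0.52, as did those of the glycerol list at -0.09 (GPP1 -0.22, DAK2 -0.14), of the trehalose and glycogen list at -0.05 (PIG1 -0.23, TPS2 -0.20) and of the list of pyruvate and acetate genes at -0.05 (CYB2 -0.29, ALD6 0.26). In the glyoxylate cycle and gluconeogenesis list 1 gene, MDH2, passed when adjusted over the list alone, and 0 did in the other 6 lists of this paragraph. These percentiles describe the pooled libraries, since genes are not independent replicates. Across genes the log2 ratio also fell with coding length (Spearman's rho = -0.336 over 5362 genes).

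The genes next to the deleted loci were called more often than others, on a small count. Of the 26 nearest tested neighbours, by gene order in the R64 reference, 2 were called: UBP15, beside ADH2, was lower and ZRT1, beside ADH4, was higher. This is 7.69%, against 38 of 5336 other genes or 0.712% (Fisher's exact test, two-sided, p = 0.0158). With a q of 0.01 in place of 0.05, 1 neighbour was left and the p was 0.153. None of the nearest neighbours of URA3, HIS3 and LEU2 was called.

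By chromosome, the sequence listed as chromosome 0 had a median log2 ratio of -0.55 over 6 genes (permutation test with 10000 random gene sets, adjusted p = 0.0017), and no other chromosome passed with the median. Over all 8 of its models, which adds ADA2 and BIO3 whose longest models lie elsewhere, the median was -0.31 with the same adjusted p, and its genes need not be linked. Of 513 windows of 20 consecutive genes, 3 had a median beyond that of all 10000 random gene sets. They were the 2 overlapping windows of the chromosome 3 block, CWH43 to FEN2 and PET18 to BUD5, with medians of 0.40 and 0.20, and the window TRP2 to SWI4 over the chromosome 5 block with 0.33. Windows of 10 genes gave 6, of which 2 lay on chromosome 15 and the others over the blocks, and windows of 40 genes gave 0. With the mean in place of the median, chromosomes 0, 3 and 5 passed.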

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

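No paired analysis was possible because the table holds 1 pooled value per strain, and leaving out each replicate in turn and the replicate block were not run for the same reason. How far a single library decides a call is therefore not known, and the depth behind each value is unknown. The settings without the 2 blocks, per gene, per model and with the correction for level, length and GC were chosen after the data were seen. Requiring a change of at least 2-fold left 20 of the 43 calls, 13 higher and 7 lower, GPM3 with its 0 among them, and with 1 FPKM added 18, of which 11 were higher and 7 lower, by construction of a stricter limit. Without the 2 blocks 24 calls were left, 9 of them higher. With a q of 0.01, 37 calls were left, and counts with recomputed q, with centring, with the FPKM minimum, per gene and without deleted and marker genes stayed within 1.5 times of the main counts. The Fisher test of the neighbours of deleted loci gave p = 0.153 with a q of 0.01, where 1 called neighbour was left, and between 0.00452 and 0.0178 under the other settings. Windows of 10 genes gave 6 windows beyond all random sets, of which AAD15 to DCP1 at 0.28 and GDH1 to PHR1 at -0.21, which spans FIT2 and FIT3, lay on chromosome 15 outside the 2 blocks, windows of 40 genes gave 0 and the mean gave 3 chromosomes past the threshold. Per model, 3 windows and 1 chromosome passed. The cause was not tested. The retained paralogs' median stayed between -0.20 and -0.16 and below the range of random lists under each setting run, and the iron regulon remained the 1 list past Fisher's test. In the score of single genes and list medians, genes that were not called counted as unchanged under every setting. A list median cannot move with the limit on q, and single genes kept the authors' q throughout. Much of the count of unchanged values was therefore fixed in advance. That count was 567, while 14 values lost their side of the threshold, 2 gained it and 8 medians of lists inside the range of random lists changed sign. With genes of an FPKM of at least 10 these were general stress (0.0036), zinc (0.0393) and flocculation (0.0300), with 1 FPKM added flocculation (2.42e-05), with centring the cell wall (-0.0111), and after the correction general stress (0.00166), meiosis (0.0346) and flocculation (0.0577). The lost ones include TIS11, YRO2, UBP15, BNA2 and PHO3 at a q of 0.01.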

Other observations

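In this part the extra-copy comparison and the fit on level, length and GC were chosen after the result was seen. So were the use of the zinc list for the supply of metals and the tests of shared reads. The shuffling of calls was also shaped after the blocks were seen, since its run length came from them. The list medians against random lists were fixed before.

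Of the lists outside central carbon metabolism with no called gene, some had a median outside the range of random lists. The methionine and sulfur assimilation list had 17 of 21 members above 0, with a median log2 ratio of 0.17 at the 99.98 percentile of matched random lists. Its methionine permease gene MUP1, at 0.55 with q = 0.0989 in the authors' deposited table, was the 1 member that passed when adjusted over the list alone, and MMP1 stood at 0.40. The ribosome biogenesis list had 36 of 44 members above 0 and a median of 0.10, with EBP2 at 0.43 and NOP16 at 0.35, while the ribosomal protein list, at 0.08 (RPP0 -0.25, RPL22A 0.23), lay inside the range of random lists. The purine list had 15 of 16 members below 0 and a median of -0.14, with GCV2 at -0.40 and SHM2 at -0.27, that became -0.09 (percentile 1.22) after the fit on level, length and GC, and the leucine and branched-chain list a median of -0.14, with BAT2 at -0.30 and ILV2 at -0.20. The lysine and arginine, ergosterol, respiratory chain and fusel alcohol lists also lay below the central 95% of random lists, with medians of -0.05, -0.06, -0.01 and -0.10. Among their members were ARG3 at -0.21, ERG12 at -0.28 and MVD1 at -0.22, NDE1 at -0.33 and CYC1 at -0.24, and EEB1 and ARO9 at -0.53 and -0.37. Each of these 4 lists left that side of the range under at least 1 other setting: lysine and arginine without A and B copies (-0.05) or after the fit on level, length and GC (-0.05), ergosterol after that fit (-0.07), fusel alcohol with an FPKM of at least 10 (-0.07) and the respiratory chain under 3 settings (-0.01, -0.02 and -0.01). After the fit the respiratory chain median was -0.06, below the range. In the fusel alcohol list EEB1, an ethyl ester synthase gene, was the 1 member to pass when adjusted over the list alone. OYE3, at -0.86, was that member in the redox defence list, whose median was -0.05 and where SOD2 stood at -0.29. The redox defence list lay inside the range of random lists, and below it after the fit (-0.07, percentile 1.63).

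Other lists lay inside the range of random lists in the setting fixed at the start and held 0 called genes. The list of sucrose, maltose and galactose use lay below the range with genes of an FPKM of at least 10 (-0.14, percentile 1.19). Their median log2 ratios were -0.03 for histidine synthesis (HIS4 -0.29, HIS6 0.25), 0.04 for pyrimidine synthesis (URA1 0.44, FUR1 -0.22) and -0.13 for sucrose, maltose and galactose use (MAL32 -0.29, SUC2 -0.25). They were 0.04 for beta-oxidation (IDP3 0.30, POT1 0.24), -0.04 for heat shock chaperones (KAR2 -0.31, SSC1 -0.19) and 0.05 for alcohol dehydrogenases outside the pathway (AAD15 0.50, AAD6 -0.26). For the phosphate regulon the median was -0.03 (SPL2 0.22, PHO12 0.17), for meiosis -0.04 (REC8 0.39, SPS4 -0.38) and for histones 0.09 (HHF2 0.17, HTB1 0.16). The anaerobic list (DAN1 -0.64, ANB1 -0.22) had a median of 0.05 and a mean of -0.02, the list of mating-type a and pheromone response genes (FIG1 -0.92, KAR4 0.36) 0.02 and -0.01, and the flocculation list (AMN1 -0.11, CLN1 0.10) -0.002 and 0.002, so that median and mean differ in sign in each. Many of these small medians depended on the setting. After the fit those of ribosomal proteins, histones, alcohol dehydrogenases and anaerobic genes were 0.04, 0.03, 0.02 and 0.01, those of sucrose, maltose and galactose use and of the phosphate regulon -0.09 and -0.01, that of mating-type a genes 0.04, and those of meiosis and flocculation turned positive at 0.03 and 0.06. With genes of an FPKM of at least 10 beta-oxidation stood at 0.01, mating-type a genes at 0.06, meiosis at -0.11 and flocculation at 0.03. The 4 markers of the opposite mating type had a median of -0.16 and 0 called genes, with MF(ALPHA)1 at an FPKM of 6.45 in the reference and 4.41 in the minimal glycolysis strain and STE3 at 9.97 and 7.63.

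The models flanking the higher blocks on chromosomes 3 and 5 were not called, but AIM11, directly before the chromosome 5 block, stood at 0.41, above the central 95% of all models (-0.31 to 0.33), so that edge is less sharp than the others. The 28 higher calls were shuffled over the tested models 10000 times. The limit of 9 for the length of a run was taken from the shorter block. There were 0 arrangements with 2 runs of at least 9, and the longest run was 3. This argues against chance placement, although the test was shaped after the blocks were seen. A candidate explanation is 1 extra copy of each block in this haploid strain, which predicts a log2 ratio of 1: the medians were 1.04 (bootstrap 95% interval 0.88 to 1.09) on chromosome 3 and 1.09 (0.95 to 1.23) on chromosome 5. This remains a hypothesis found and tested on the same data, and RNA values do not measure copy number. Each block is a run of models already called higher, and no called model had an absolute log2 ratio under 0.65. Genes nearer to no change could thus not enter a block. The intervals resample these selected genes, so their cover of 1 is in part a result of the selection. By gene order in R64, a long terminal repeat, mobile element or tRNA gene lies outside both edges of the chromosome 3 block. Such an element lies at neither edge of the chromosome 5 block, and between 5.2% of all neighbouring gene pairs. The left edge on chromosome 3 was scored between CWH43 and MAK32, but in the authors' assembly the tested model before MAK32 is CTO1. For that edge the R64 interval therefore need not be the one beside the block.

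The iron regulon was lower as a group. A bias by gene length, GC content and expression level was argued against, since after a fit on these properties its median was -0.32 and still below the central 95% of matched random lists (-0.07 to 0.07). A difference between the cultures in the supply of several metals stays open: the zinc list had a median of -0.039 with 7 members above 0 and 9 below, and of 0.04 with genes of an FPKM of at least 10, which decides nothing, and iron alone could differ between bioreactors. The zinc transporter gene ZRT1 and the copper transporter gene CTR3 were called in the direction opposite to the iron genes, at 1.68-fold and 1.75-fold. ZRT1 is also the nearest tested gene to the right of the deleted ADH4 locus, so its call need not reflect the supply of zinc. An effect of the genotype on iron demand may also account for it and was not tested, because strain and cultures cannot be told apart in pooled values.

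The retained glycolytic paralogs were slightly lower as a group. The fit on gene length, GC content and expression level left their median at -0.16, below the central 95% of matched random lists (-0.08 to 0.11), which argues against those properties as the whole cause. Reads shared with deleted paralogs could raise the reference value of a retained gene, but PGI1, PFK1, PFK2, TPI1 and PGK1, which had no deleted paralog, had a median of -0.20 against a range of -0.12 to 0.18. For HXK2, GPM1, CDC19, PDC1 and ADH3, which had one, shared reads stay open: their mean was -0.18 and that of the others -0.20, with p = 0.722 (exact permutation test, two-sided). An effect of the genotype stays open as a biological explanation and was not tested.

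The amino acid permease genes were looked at as a family because BAP3, AGP1, DIP5 and GNP1 were called, so no test of the family is given. The 16 others in the family ranged from -0.26 for AGP2 to 0.55 for MUP1, with 8 above 0 and 8 below.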
